A study of Homo sapiens with 226 samples.

How the data were processed

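Total RNA from tumours, normal lung and airway brushings was labelled as biotinylated cRNA and hybridised to Affymetrix Human Gene 1.0 ST arrays. The deposited table holds log2 signals of 33252 probe sets on 226 arrays, made by the authors with RMA (background correction, quantile normalisation and summary of probes; no version given). The values were used as deposited, with no added pseudocount. Of the probe sets, 19460 carried 1 gene symbol, 1754 several and 12038 none. 19429 of those with 1 symbol matched a current symbol, 24 for X-inactivation transcripts or Y-linked genes were left out of all fits, and 18394 genes were tested. 768 genes had several probe sets, of which the one with the highest mean over all arrays stood for the gene. No genome build was named with the probe annotation, so no coordinates are given. 0 columns of the table were left unused.

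Samples were grouped by the deposited labels for tumour type, site, collection and patient, and airways by their labelled distance rank. The patient was the replicate. Differences were taken within patients, airways being averaged over ranks and tumour minus normal lung differences over the collection methods (up to 3) in which a patient had both, and 1 value per patient was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Airways and tumours were compared in brushings, shared changes with tumour tissue on 1 side and airway brushings on the other so that no array served both. Distance was fitted as a slope per rank on single airway arrays with patient as fixed block, and tumour types were compared between patients. All p values are two-sided. Adjusted p values of single genes are after Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Counts were also taken with a log2 difference of at least 1. Permutation p values are unadjusted unless called adjusted, and the adjustment of lists is given below. The number of arrays limits the precision.

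Comparisons and their statistical tests, 24 gene lists (348 genes, 321 measured) and the rule for named genes were fixed before the data were examined. Tests of explanations were added later, 2 of them after their results had been seen. The rule took the 10 highest and 10 lowest differences among genes past the threshold that went the same way in at least 90% of patients (for distance 70% of patients with 3 or more airways). It also took the 3 smallest p values per direction where none passed, up to 4 members per list with the largest difference past the threshold, LAPTM4B in every comparison, and for shared changes the 10 genes per direction with the largest smaller difference. Fewer are printed for length, in rank order. In the account of opposite directions, CCDC39 comes from the list part of that rule. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a fit. Fry tests whether a list's genes moved on balance 1 way and does not compare them with other genes. The estimated correlation kept 1 list call in NSCLC tumours against normal lung, 1 in carcinoid against NSCLC differences and 1 in the slope difference, and 0 in each other comparison. In the distance trend, list means were also tested with 100000 permutations of ranks within patients, adjusted over the 24 lists, and 2 sets of 200 genes with the largest tumour differences in each direction were tested with camera (p unadjusted unless called adjusted, which is over the 2 sets).

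Alternatives were a second quantile normalisation, centring on array medians, leaving out the 40% of genes with the lowest means, the mean of probe sets, a trended robust prior and no patient block. Others were single collection methods, closest or farthest airways alone, tissue in place of brushings, other forms of the distance rank, a random patient block and leaving out patients. Arrays standing apart were those whose spread around the median array of their tissue exceeded the group's median by 3 scaled MADs (13 of 226).

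The fits were tested on simulated data in which 200 of 18394 genes were changed. Genes were drawn independently of each other and slopes were alike in all patients, so the shares recovered hold for those settings alone. Of differences of 0.5 and 1 log2 units, 78% and 98% were recovered for NSCLC tumour against normal lung (6 false calls) and 88% and 99% for airway against normal lung (9 false calls). With 3 carcinoid patients 38% of differences of 1 and 87% of differences of 3 were recovered (6 false calls), and slopes of 0.1 and 0.2 per rank were recovered at 91% and 99% (7 false calls). In 20 simulated groups with unchanged genes the count of shared genes was 0 in each. These groups had independent genes and 1 normal lung brushing per patient on both sides, unlike the reported count with separate normal lung arrays. They therefore do not bear on the size of that count. Pairing was checked by the correlation of deviations from group means: frozen and RNAlater samples of a patient's tumour had a median of 0.850 and those of normal lung 0.500, against −0.080 and −0.023 between patients. 1 of 17 tumour and 1 of 19 normal lung pairs did not deviate together (correlation of 0.1 or less). The highest correlation between any pair of arrays was 0.996, and 0 pairs were identical. The arrays of that most alike pair were labelled as different patients, and the result of leaving them out is given below. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.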

Results

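Gene expression was measured on 226 arrays from 23 patients with lung cancer, 20 with non-small cell lung cancer (NSCLC) and 3 with a carcinoid, a lung tumour of neuroendocrine cells. Each patient gave tumour, normal lung away from the tumour, and brushings of airways ranked from 1 (closest to the tumour) to 5 (farthest). Not every patient had every rank. NSCLC patients gave 2 to 5 airway brushings each and carcinoid patients 5, so airway means per patient cover unlike ranks. Tumour and normal lung were collected in up to 3 ways, as frozen tissue, as tissue kept in RNAlater (a solution that preserves RNA) and as brushings. The NSCLC patients gave 81 airway brushings, 20 RNAlater, 19 frozen and 19 brushed samples of normal lung, and 19 RNAlater, 18 frozen and 18 brushed samples of tumour. The carcinoid patients gave 15 airway brushings, 8 samples of normal lung (3 RNAlater, 3 frozen and 2 brushed) and 9 of tumour (3 of each kind). Array medians lay between 7.33 and 7.55 on the log2 scale. 13 of the 226 arrays stood apart from their group in spread, 7 of them NSCLC airway brushings. Values are log2 differences ± SE of the fit, over patients for differences and over single airway arrays within patients for slopes with distance.

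The first comparison asked which genes differed between NSCLC tumours and the normal lung of the same patients. Tumours had more SPP1, the secreted matrix protein osteopontin (3.97 ± 0.26, higher in 20 of 20 patients, adjusted p = 2.8e-10), and more of the macrophage elastase MMP12 (3.22 ± 0.36, 20 of 20, adjusted p = 3.2e-07). SPINK1, MMP1, TMPRSS4 and the B cell attractant CXCL13 followed, at 3.01 ± 0.54, 2.90 ± 0.42, 2.81 ± 0.30 and 2.73 ± 0.30, each higher in 19 of 20 patients. The deepest falls were in the serotonin transporter SLC6A4 (−4.29 ± 0.30, lower in 20 of 20, adjusted p = 6.4e-10), the fatty acid binding protein FABP4 of alveolar macrophages (−4.19 ± 0.27), TMEM100 (−3.91 ± 0.20), the Wnt inhibitor WIF1 (−3.82 ± 0.28) and AGER, the receptor abundant on flat alveolar cells (−3.56 ± 0.16, adjusted p = 4.0e-12), each lower in 20 of 20. LAPTM4B, a lysosomal membrane protein that the published study of these samples followed up, was higher by 1.34 ± 0.12 in 20 of 20 patients (adjusted p = 8.7e-09). Of 18394 genes, 9062 passed an adjusted p of 0.05, 5318 higher and 3744 lower, and 954 of them differed by at least 1 log2 unit (344 higher, 610 lower).

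All 22 proliferation genes rose in NSCLC tumours, 22 also when adjusted over the list alone, among them the DNA topoisomerase TOP2A (2.53 ± 0.23), the mitotic protein CENPF (2.05 ± 0.24), TPX2 (2.01 ± 0.26) and CCNB2 (2.00 ± 0.25), each higher in 20 of 20 patients. The list had an adjusted p = 1.2e-10 (adjusted p = 0.28 with an estimated correlation). Of 21 fibroblast and extracellular matrix genes 16 rose and 2 fell, the same counts when adjusted over the list alone. THBS2 (1.73 ± 0.16) and the fibroblast protease FAP (1.70 ± 0.19) led them, each higher in 19 of 20 patients (list adjusted p = 0.00023; adjusted p = 0.34 with an estimated correlation). 9 of 10 B and plasma cell genes rose (10 adjusted over the list alone). Among them were the B cell surface protein MS4A1 (1.67 ± 0.31) and CD79A (1.54 ± 0.24), each in 18 of 20 patients (list adjusted p = 0.00028; adjusted p = 0.34 with an estimated correlation). Among 13 genes common to epithelial cells 11 rose, and 11 when adjusted over the list alone. The transcription factor GRHL2 led (1.21 ± 0.12, 20 of 20; list adjusted p = 0.00023; adjusted p = 0.28 with an estimated correlation). 11 of 14 glycolysis and hypoxia genes rose, with 11 adjusted over the list alone. The glucose transporter SLC2A1 led (1.93 ± 0.27, 20 of 20; list adjusted p = 0.00028; adjusted p = 0.31 with an estimated correlation). 8 of 10 heat shock genes rose (8 up and 1 down adjusted over the list alone), HSPD1 by 0.61 ± 0.07 in 20 of 20 patients (adjusted p = 0.0035; adjusted p = 0.29 with an estimated correlation). 8 of 13 squamous differentiation genes rose, 9 adjusted over the list alone, led by the desmosome protein DSG3 (1.60 ± 0.53), which was higher in 12 of 20 patients (adjusted p = 0.049; adjusted p = 0.54 with an estimated correlation).

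12 lists were called as lower in NSCLC tumours with the preset correlation, 1 of them also with an estimated one. All 16 endothelial genes fell, 16 adjusted over the list alone. FCN3 (−3.20 ± 0.21) and EDNRB (−2.93 ± 0.17) led them, each lower in 20 of 20 patients (list adjusted p = 1.2e-18; adjusted p = 0.064 with an estimated correlation). 9 of 12 alveolar type 1 cell genes fell, 9 adjusted over the list alone, AGER first and RTKN2 next (−3.17 ± 0.24). This was the 1 list of the 24 whose call held with an estimated correlation (adjusted p = 0.032). 9 of 13 alveolar type 2 cell genes fell (9 adjusted over the list alone), led by the surfactant protein gene SFTPC (−2.81 ± 0.36, 20 of 20; list adjusted p = 1.7e-05; adjusted p = 0.20 with an estimated correlation). All 14 macrophage genes fell, 14 adjusted over the list alone, FABP4 most and the nuclear receptor PPARG next (−1.64 ± 0.20, 19 of 20; adjusted p = 0.12 for the list with an estimated correlation). 10 of 11 neutrophil genes fell, 10 adjusted over the list alone, led by S100A12 (−1.56 ± 0.21, lower in 18 of 20; adjusted p = 0.17 for the list with an estimated correlation). All 9 smooth muscle genes fell, 9 adjusted over the list alone, led by desmin, DES (−1.27 ± 0.09, 20 of 20; adjusted p = 0.19 with an estimated correlation). This average over collection methods came largely from tissue. In the 17 patients with both, the mean difference in brushings and in tissue was −0.49 and −1.76 for DES, −0.16 and −1.90 for ACTG2, and 0.28 and −1.10 for PLN. All 6 erythroid genes fell, 6 adjusted over the list alone, led by the beta globin gene HBB (−2.11 ± 0.18; adjusted p = 0.19 with an estimated correlation). 3 of 5 mast cell genes fell, 3 adjusted over the list alone, led by HPGDS (−1.26 ± 0.26; adjusted p = 0.34 with an estimated correlation). 16 of 20 ciliated cell genes fell, 16 adjusted over the list alone, led by TPPP3 (−1.49 ± 0.22, lower in 18 of 20; adjusted p = 0.38 with an estimated correlation). 12 of 16 immediate early genes fell and 1 rose, the same adjusted over the list alone, led by FOSB (−2.44 ± 0.33, lower in 19 of 20; adjusted p = 0.37 with an estimated correlation). 7 of 14 T and NK cell genes fell (7 adjusted over the list alone), led by the interleukin 7 receptor IL7R (−1.31 ± 0.22). 9 of 18 interferon genes fell while CXCL9 rose by 1.12 ± 0.37 (9 down and 2 up adjusted over the list alone). Both lists had an adjusted p = 0.54 with an estimated correlation.

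5 lists were not called in NSCLC tumours. Of 11 airway basal cell genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.092), with KRT15 at 1.55 ± 0.38 in 15 of 20 patients. Of 15 airway secretory cell genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.64), the club cell protein SCGB1A1 falling by 2.27 ± 0.50 in 17 of 20 patients. Of 15 xenobiotic and oxidant response genes 5 rose, 5 adjusted over the list alone, led by GPX2 (2.08 ± 0.49, 14 of 20; list adjusted p = 0.092). Of 7 MHC class II genes 4 fell, 4 adjusted over the list alone (adjusted p = 0.079). Of 16 neuroendocrine genes 3 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.94). Lists were tested with camera of limma at a preset correlation, which called 19 of 24, and fry called 19.

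**Figure D1:**
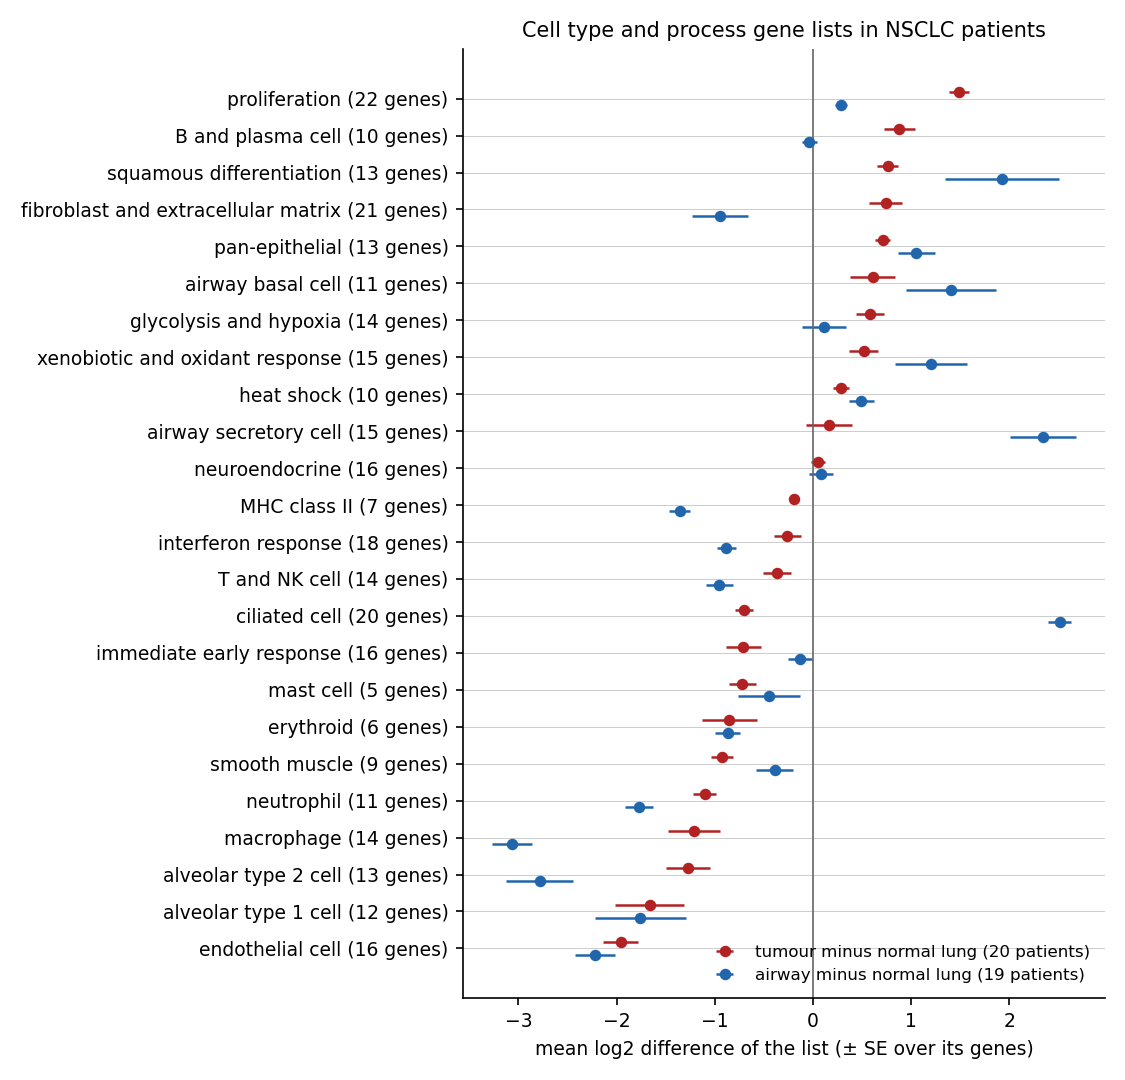
Mean log2 difference of each of the 24 gene lists (horizontal axis) in NSCLC tumours (red, 20 patients) and in airway brushings (blue, 19 patients) against normal lung, with bars of ± SE over the genes of the list. The endothelial list lay at −1.96 in tumours and −2.22 in airways, the ciliated cell list at −0.70 and 2.51.

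The airway comparison asked how airway brushings of NSCLC patients differed from brushings of their normal lung. Airways had more of the squamous cell serpin SERPINB3 (5.70 ± 0.45, 19 of 19 patients, adjusted p = 3.3e-10), of MSMB, a secreted protein of airway secretory cells (5.08 ± 0.46), of SERPINB11 (5.01 ± 0.32), and of UPK1B (4.98 ± 0.18), each higher in 19 of 19 patients. They had less FABP4 (−4.73 ± 0.22, lower in 19 of 19, adjusted p = 1.1e-13), less of the alveolar protease NAPSA (−4.42 ± 0.20), less surfactant protein SFTPB (−4.42 ± 0.24) and less WIF1 (−4.34 ± 0.16), each in 19 of 19. Of 18394 genes 12355 passed, 5910 higher and 6445 lower, with 2250 at 1 log2 unit or more (1167 higher, 1083 lower).

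The ciliated, secretory and basal cell lists of the airway were higher and the lists of the alveolus lower. All 20 ciliated cell genes rose (20 adjusted over the list alone), led by SNTN of the ciliary tip (3.20 ± 0.33, 18 of 19). All 15 airway secretory genes rose, 15 adjusted over the list alone, with MUC5B, a gel-forming mucin, at 3.38 ± 0.29 in 19 of 19. 9 of 11 basal cell genes rose and 1 fell, the same adjusted over the list alone, led by the basal keratin KRT5 (4.10 ± 0.13, 19 of 19). 10 of 15 xenobiotic response genes rose while 3 fell, the same adjusted over the list alone, led by the alcohol dehydrogenase ADH7 (3.98 ± 0.14, 19 of 19). All 14 macrophage genes, all 16 endothelial genes and all 13 alveolar type 2 genes fell, the same adjusted over the list alone. Their examples were MRC1 at −4.15 ± 0.17, PECAM1 at −3.33 ± 0.14 and SFTPC at −4.08 ± 0.23, each lower in 19 of 19. 17 of 18 interferon genes and all 7 MHC class II genes fell as well, 17 and 7 adjusted over the list alone, with IFIT2 at −1.84 ± 0.09 and HLA-DMB at −1.63 ± 0.12 in 19 of 19. These 9 lists had adjusted p values from 1.8e-10 (macrophage) to 0.0026 (xenobiotic response), and each had an adjusted p = 0.22 with an estimated correlation. Proliferation genes were not called as a list: 8 of 22 rose, 5 adjusted over the list alone, CDK1 by 0.86 ± 0.13 in 17 of 19 (list adjusted p = 0.053). Camera called 17 of 24 lists with the preset correlation, and fry called 19. LAPTM4B did not pass (0.27 ± 0.16, higher in 14 of 19, adjusted p = 0.14). With normal lung tissue in place of brushings its difference turned to −0.64 (adjusted p = 3.7e-05).

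To look for a profile common to tumour and airway, calls in tumour tissue (frozen and RNAlater, 20 patients) were set beside calls in airway brushings (19 patients), each against its own normal lung arrays. 5046 genes changed the same way in both, 2690 higher and 2356 lower, where independent lists would share 1787 and 1282. The membrane protease TMPRSS4 (2.87 ± 0.32 in tumour tissue, 3.86 ± 0.15 in airways), the copper carrier ceruloplasmin, CP (2.35 ± 0.41 and 2.76 ± 0.28), the cell adhesion protein CDH3 (2.35 ± 0.24 and 2.60 ± 0.16), the desmosome protein DSP (2.18 ± 0.27 and 2.75 ± 0.19) and SLC2A1 (1.96 ± 0.27 and 2.35 ± 0.13) led the genes higher in both. FABP4 (−4.12 ± 0.28 and −4.73 ± 0.22), WIF1 (−3.83 ± 0.28 and −4.34 ± 0.16), SLC6A4 (−4.61 ± 0.30 and −3.50 ± 0.36) and TMEM100 (−4.21 ± 0.18 and −3.47 ± 0.32) led those lower in both. Among the lists, 16 of 16 endothelial, 11 of 14 macrophage, 10 of 11 neutrophil, 9 of 13 alveolar type 2 and 9 of 12 alveolar type 1 genes were lower in both, while 10 of 13 pan-epithelial, 8 of 11 basal cell, 8 of 22 proliferation and 6 of 10 heat shock genes were higher in both. These counts per list were not tested against chance. LAPTM4B was not shared (1.08 ± 0.12 in tumour tissue, adjusted p = 1.7e-07, and 0.27 ± 0.16 in airways, adjusted p = 0.14). With a log2 difference of at least 1 required on both sides, 471 genes were shared, 91 higher and 380 lower, where independent lists would share 22.9 and 38.6.

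Tumour brushings were then compared with airway brushings of the same 18 NSCLC patients. Tumours had more SPP1 (4.06 ± 0.28, 18 of 18, adjusted p = 3.4e-10), more SCGB3A2 (3.96 ± 0.35, 17 of 18) and more NAPSA (3.89 ± 0.37, 18 of 18). They had less SERPINB11 (−5.45 ± 0.30, lower in 18 of 18, adjusted p = 3.2e-11), SERPINB3 (−5.42 ± 0.58) and CHST9 (−4.90 ± 0.35). LAPTM4B was higher in tumours by 1.63 ± 0.20 in 17 of 18 patients (adjusted p = 1.0e-06). 9909 genes passed, 6188 higher and 3721 lower in tumours, with 1665 at 1 log2 unit or more (609 higher, 1056 lower). All 22 proliferation genes rose, 22 adjusted over the list alone, with TOP2A at 1.70 ± 0.20 and MKI67, the source of the Ki-67 antigen, at 1.53 ± 0.16, each in 18 of 18. The list had an adjusted p = 3.5e-06 (adjusted p = 0.49 with an estimated correlation). 19 of 21 fibroblast and matrix genes rose, 20 adjusted over the list alone, led by lumican, LUM (3.33 ± 0.27, 18 of 18; adjusted p = 0.38 with an estimated correlation). 13 of 18 interferon genes rose, 14 adjusted over the list alone, led by the chemokine CXCL10 (2.27 ± 0.29, 18 of 18; adjusted p = 0.49 with an estimated correlation). Markers of other cell types rose beside these. 13 of 14 macrophage genes rose, 13 adjusted over the list alone, led by APOC1 (2.42 ± 0.21, 18 of 18; adjusted p = 0.38 with an estimated correlation). 13 of 16 endothelial genes, 10 of 14 T and NK cell genes and 9 of 10 B and plasma cell genes rose, 14, 11 and 9 adjusted over the list alone. Examples were PECAM1 (1.68 ± 0.15, 18 of 18), IL7R (1.07 ± 0.24, 15 of 18) and JCHAIN (1.61 ± 0.48, 14 of 18), with list adjusted p = 0.45, 0.54 and 0.49 with an estimated correlation. All 20 ciliated cell genes fell, 20 adjusted over the list alone, with SNTN at −4.62 ± 0.29. 13 of 15 secretory genes fell, 14 adjusted over the list alone, with MSMB at −4.88 ± 0.60. Both lists had an adjusted p = 0.38 with an estimated correlation. Camera called 15 of 24 lists with the preset correlation and 0 with an estimated one, and fry called 19.

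The distance trend asked which genes of NSCLC airways varied with distance from the tumour, as a slope per rank over 81 airway brushings of 20 patients. Directions of single genes are given for the 19 patients with 3 or more airways. The chemokine CCL20 fell by 0.25 ± 0.068 per rank (14 of 19 patients, adjusted p = 0.029), followed by the matrix peroxidase PXDN (−0.17 ± 0.036, 15 of 19), the urokinase gene PLAU (−0.16 ± 0.039, 16 of 19) and MKI67 (−0.16 ± 0.040, 15 of 19, adjusted p = 0.019). LAPTM4B also fell with distance (−0.16 ± 0.036, 14 of 19, adjusted p = 0.013; permutation of ranks within patients p = 0.00031). FER1L6 (0.17 ± 0.035, 14 of 19, adjusted p = 0.012), HSD17B13 (0.17 ± 0.037, 16 of 19), SERPINB11 (0.16 ± 0.035, 14 of 19) and the aminopeptidase ANPEP (0.15 ± 0.030, 16 of 19) rose with distance. 782 genes passed, 260 rising and 522 falling, so that 33.2% rose. With arrays quantile normalised again 803 passed with 46.8% rising, and with arrays centred on their medians 766 with 60.3% rising.

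These calls rested on 1 of the 20 patients. Without that patient no gene passed in limma (1960 at an unadjusted p under 0.05) and the slope of LAPTM4B was −0.094 (adjusted p = 0.29). Without any other single patient 283 to 1464 genes passed. No gene passed in limma either with 1 slope per patient (2552 at an unadjusted p under 0.05), with the farthest set against the closest airway (1069), or in the patients with airways at all 5 ranks (1188). Nor did any pass without the patient block (3503 at an unadjusted p under 0.05) or without the arrays standing apart (2715). A count of 35 passed with ranks scaled within patients. Without the airways at rank 5, the farthest, 152 passed (73 rising, 79 falling), and the slope of LAPTM4B was −0.057 ± 0.043 (adjusted p = 0.56).

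Over all patients and ranks, genes higher in tumours tended to fall away from the tumour. Of the 522 falling genes, 396 (75.9%) were among those higher in NSCLC tumours than in normal lung, where independent lists would share 150.9, and 18 were among those lower. Of the 260 rising genes 128 were lower in tumours, where independent lists would share 52.9. The 200 genes with the largest tumour difference had a mean slope of −0.065 per rank, with 46 falling and 0 rising. Their mean fell in 16 of 19 patients (camera p = 9.2e-21; p = 0.035 with an estimated correlation, adjusted p = 0.070; permutation of ranks within patients p = 0.0016). The 200 genes with the deepest fall in tumours had a mean slope of 0.043, with 9 rising, in 11 of 19 patients (camera p = 1.7e-14; p = 0.13 with an estimated correlation; permutation p = 0.10). The mean of the genes higher in tumours was 0.048, 0.052, −0.019 and 0.007 at ranks 1 to 4 and −0.156 at rank 5. Without the airways at rank 5 the mean slopes of both sets were below 0, at −0.031 and −0.053. The fall was then not particular to genes higher in tumours. The overlaps rest on calls that ended without 1 patient, and the sets were not tested without that patient. The overlaps were counted with the deposited scaling alone. The number of falling genes depended on scaling, at 427 with arrays quantile normalised again and 304 with arrays centred on their medians.

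Of the lists, proliferation genes had the largest mean slope along the airways: 12 of 22 fell and 10 did not pass, 22 falling when adjusted over the list alone, with a mean slope of −0.10 per rank. TOP2A was at −0.17 ± 0.049, MKI67 at −0.16 ± 0.040 and TPX2 at −0.15 ± 0.039 (list adjusted p = 7.7e-15; adjusted p = 0.46 with an estimated correlation). Their mean fell in 14 of 19 patients, which missed the threshold after adjustment over lists (permutation adjusted p = 0.054). The mean slope was −0.042 without the 1 patient on whom the calls rested. Of 14 glycolysis and hypoxia genes 3 fell (8 adjusted over the list alone), ENO1 by 0.088 ± 0.024 in 16 of 19 patients. The list mean was −0.043 (adjusted p = 0.00012; adjusted p = 0.46 with an estimated correlation; permutation adjusted p = 0.054), and −0.026 without the same patient. Of 18 interferon genes 2 fell (12 adjusted over the list alone), IFI27 by 0.13 ± 0.037 in 11 of 19 patients. The list mean was −0.079 (adjusted p = 1.4e-06; adjusted p = 0.46 with an estimated correlation; permutation adjusted p = 0.079). Without the same patient it was −0.028. The erythroid list, markers of blood, had a mean slope of 0.091, above 0 in 13 of 19 patients, with 0 of 6 genes passing and 4 when adjusted over the list alone (adjusted p = 0.00022; adjusted p = 0.46 with an estimated correlation; permutation adjusted p = 0.079). It was 0.080 without the same patient and 0.044 without the airways at rank 5. The ciliated cell list had a mean slope of 0.028 with 0 of 20 genes passing, 0 adjusted over the list alone (adjusted p = 0.00012; adjusted p = 0.82 with an estimated correlation). Camera called 8 of 24 lists with the preset correlation and none with an estimated one, fry called 3, and the permutation of ranks called none.

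**Figure D2:**
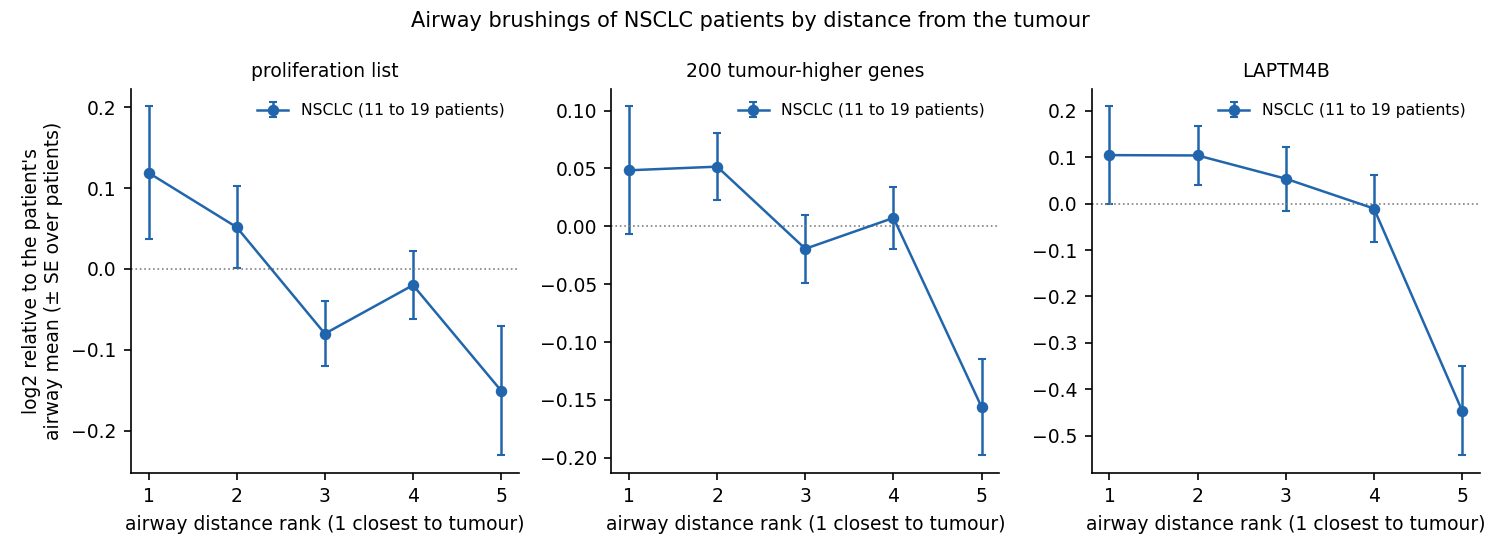
Mean log2 level of the 22 proliferation genes, of the 200 genes with the largest tumour difference and of LAPTM4B in NSCLC airway brushings, each relative to the patient's own airway mean (vertical axes, bars ± SE over 11 to 19 patients), by distance rank (horizontal axes, 1 closest). At ranks 1, 4 and 5 the means were 0.12, −0.02 and −0.15 for proliferation, 0.05, 0.01 and −0.16 for the 200 genes, and 0.10, −0.01 and −0.45 for LAPTM4B, with 11 patients at rank 5.

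Collection method was examined because the airways were sampled by brushing alone. In normal lung, brushings had more of the neutrophil chemokine receptor CXCR1 (1.68 ± 0.21, 18 of 19 patients, adjusted p = 7.9e-07), more S100A12 (1.65 ± 0.24, 18 of 19) and more ADTRP (1.61 ± 0.12, 19 of 19) than tissue. They had less of the smooth muscle actin ACTG2 (−2.81 ± 0.18, lower in 19 of 19, adjusted p = 2.3e-10), ASPN (−2.55 ± 0.17) and OGN (−2.51 ± 0.15). All 11 neutrophil, 14 macrophage and 6 erythroid genes rose and all 9 smooth muscle genes fell, the same adjusted over the list alone, with MSR1 at 1.33 ± 0.11 and MYH11 at −2.32 ± 0.17. 15 of 16 endothelial genes fell, 15 adjusted over the list alone, CALCRL by 1.54 ± 0.23. 14 of 21 fibroblast genes fell while 3 rose, the same adjusted over the list alone, POSTN by 1.96 ± 0.21 in 19 of 19. These 6 lists passed with the preset correlation, and their adjusted p was 0.51 to 0.57 with an estimated correlation. LAPTM4B was lower in brushings (−0.91 ± 0.10, 19 of 19, adjusted p = 1.9e-07). 12525 genes passed, 7147 higher and 5378 lower, 432 of them by at least 1 log2 unit (132 higher, 300 lower). A count of 7766 passed without the 40% of genes with the lowest means.

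In tumours, brushings had more HBB (2.34 ± 0.16, 18 of 18, adjusted p = 1.6e-08), TREM1 (1.07 ± 0.17) and S100A12 (1.02 ± 0.19), each in 18 of 18 patients. They had less ADGRL4 of endothelial cells (−1.56 ± 0.12, lower in 18 of 18), complement C7 (−1.55 ± 0.20) and SPARCL1 (−1.47 ± 0.14). All 11 neutrophil and 6 erythroid genes rose, and all 9 smooth muscle and 20 of 21 fibroblast genes fell, the same adjusted over the list alone, ACTG2 by 1.17 ± 0.15 and POSTN by 1.41 ± 0.17 (adjusted p = 0.17 to 0.19 with an estimated correlation). No proliferation gene of 22 passed, 0 adjusted over the list alone, and LAPTM4B did not differ past the threshold (−0.07 ± 0.08, adjusted p = 0.55). 5287 genes passed, 2407 higher (45.5%) and 2880 lower, with 55 at 1 log2 unit or more (8 higher, 47 lower). The majority turned with scaling: 5674 passed when quantile normalised again (53.4% higher) and 5819 when centred on medians (55.1% higher). Without the patient block 157 passed.

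The tumour minus normal lung difference itself depended on collection in 3879 genes, 2154 with a higher and 1725 with a lower difference in brushings than in tissue (17 patients, 42 genes at 1 log2 unit or more). The difference was higher in brushings for the muscle genes ACTG2 (1.73 ± 0.22, 17 of 17, adjusted p = 8.0e-05) and SYNPO2 (1.54 ± 0.22, 16 of 17). It was lower for INHBA, a subunit of activin (−1.77 ± 0.16, lower in 16 of 17, adjusted p = 2.5e-06), and the cytokine IL1A (−1.16 ± 0.20, 16 of 17). 8 of 9 smooth muscle genes had a higher difference, 9 adjusted over the list alone, and 10 of 11 neutrophil genes a lower one, 10 adjusted over the list alone (adjusted p = 4.4e-10 and 3.7e-06; adjusted p = 0.52 and 0.61 with an estimated correlation). LAPTM4B showed a tumour difference larger in brushings by 0.88 ± 0.11 in 16 of 17 patients (adjusted p = 8.5e-05).

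Fewer genes differed between RNAlater and frozen tissue. In normal lung, RNAlater tissue had more CLC, the eosinophil and basophil galectin (1.79 ± 0.19, 19 of 19, adjusted p = 2.2e-05), S100A12 (1.31 ± 0.18, 18 of 19) and the mast cell carboxypeptidase CPA3 (1.28 ± 0.27, 18 of 19) than frozen tissue. It had less vault RNA VTRNA1-1 (−1.19 ± 0.12, lower in 18 of 19) and small nucleolar RNA SNORA38B (−0.75 ± 0.10, 19 of 19). 10 of 14 T and NK cell genes rose, 13 adjusted over the list alone, CD3G by 0.61 ± 0.08 in 19 of 19 (adjusted p = 3.8e-15; adjusted p = 0.14 with an estimated correlation). 4 of 5 mast cell genes rose, 4 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). LAPTM4B did not pass (0.11 ± 0.05, adjusted p = 0.30). 1045 genes passed, 760 higher and 285 lower, with 4 at 1 log2 unit or more. A count of 571 passed with a trended robust prior, 73 without the patient block, and 466 without the pair of arrays most alike.

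In tumours, RNAlater tissue again had more CLC (1.42 ± 0.22, 16 of 17, adjusted p = 0.0038), PRELP (0.66 ± 0.12, 16 of 17) and FRZB (0.63 ± 0.11, 16 of 17). It had less SNORA38B (−1.18 ± 0.13, lower in 17 of 17, adjusted p = 0.00019), HBB (−0.92 ± 0.14, 16 of 17) and SNORA2A (−0.87 ± 0.13, 17 of 17). 2 of 5 mast cell genes rose, 4 adjusted over the list alone (adjusted p = 0.003; adjusted p = 0.34 with an estimated correlation), with CPA3 at 0.87 ± 0.19 in 15 of 17. LAPTM4B did not pass (0.24 ± 0.10, adjusted p = 0.20). 547 genes passed, 468 higher (85.6%) and 79 lower. A count of 395 passed when quantile normalised again (63.5% higher) and 392 when centred on medians (74.2% higher). With a trended robust prior 0 passed in limma (3061 at an unadjusted p under 0.05), and 3 passed without the patient block.

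The carcinoids were compared with the normal lung of the same 3 patients. Carcinoids had more of the glycine transporter SLC6A5 (6.85 ± 0.33, adjusted p = 0.0044), of GP2 (6.79 ± 0.14), of TPH1, the enzyme that begins serotonin synthesis (6.66 ± 0.44), and of the secretory granule protein SCG2 (6.46 ± 0.22), each higher in 3 of 3 patients. They had less CYP2B7P (−5.90 ± 0.11, adjusted p = 0.0018), the phosphate transporter SLC34A2 of alveolar type 2 cells (−5.85 ± 0.20), WIF1 (−5.83 ± 0.15) and RTKN2 (−5.77 ± 0.34), each lower in 3 of 3. 13 of 16 neuroendocrine genes rose, 15 adjusted over the list alone, among them SCG3 (6.09 ± 0.13) and CHGB (5.74 ± 0.34). The list had an adjusted p = 3.0e-09 (adjusted p = 0.32 with an estimated correlation). 12 of 13 alveolar type 2 genes, 13 of 14 macrophage genes and 14 of 14 T and NK cell genes fell, 13, 14 and 14 adjusted over the list alone. These lists had an adjusted p = 0.32, 0.32 and 0.41 with an estimated correlation. None of the 22 proliferation genes passed, 0 adjusted over the list alone, and LAPTM4B did not (1.02 ± 0.41, higher in 3 of 3, adjusted p = 0.15). 4536 genes passed, 2252 higher and 2284 lower, with 2247 at 1 log2 unit or more (794 higher, 1453 lower). The median over all genes was 0.10. Leaving out each patient in turn gave 0 to 6666 genes (4624 or more at an unadjusted p under 0.05 in limma).

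The tumour minus normal lung difference was also compared between the 3 carcinoid and the 20 NSCLC patients. It was higher in carcinoids for TPH1 (6.95 ± 0.31), SLC6A5 (6.85 ± 0.19) and GP2 (6.52 ± 0.55, adjusted p = 3.5e-09). It was lower for CP (−5.65 ± 1.02, adjusted p = 0.00024), the antibody joining chain JCHAIN (−5.54 ± 0.84) and the integrin ITGB6 (−5.28 ± 0.48). All 16 neuroendocrine genes were higher, 16 adjusted over the list alone, SCG2 by 6.39 ± 0.20 and SCG3 by 6.15 ± 0.11. This call held with an estimated correlation (adjusted p = 3.8e-06). 15 of 21 fibroblast and matrix genes were lower, 16 adjusted over the list alone, with LUM at −3.89 ± 0.38 (adjusted p = 0.20 with an estimated correlation). All 7 MHC class II genes were lower, 7 adjusted over the list alone, with HLA-DMA at −2.64 ± 0.36 (adjusted p = 0.17 with an estimated correlation). Immune cell markers were lower beside them. They were 10 of 14 macrophage genes, with MSR1 at −2.40 ± 0.32, 8 of 14 T and NK cell genes, with IL7R at −4.23 ± 0.61, and 6 of 10 B and plasma cell genes, with MS4A1 at −2.85 ± 0.82 (10, 9 and 7 adjusted over the list alone). These lists had an adjusted p = 1.8e-08, 6.8e-06 and 0.0012 (0.17, 0.44 and 0.44 with an estimated correlation). 9 of 22 proliferation genes were lower, 11 adjusted over the list alone, with TOP2A at −2.48 ± 0.62 (adjusted p = 1.9e-06; adjusted p = 0.44 with an estimated correlation). LAPTM4B did not pass (−0.31 ± 0.35, adjusted p = 0.57). 4234 genes passed, 2411 higher and 1823 lower, with 2117 at 1 log2 unit or more. A count of 2735 passed without the 40% of genes with the lowest means. Without each carcinoid patient in turn 2525 to 3651 passed.

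Airways of carcinoid and NSCLC patients, averaged over the ranks that each patient had, gave 0 genes past the threshold in limma (2182 at an unadjusted p under 0.05). The smallest p values belonged to the neuroendocrine granule protein CHGA (0.34 ± 0.06 higher in carcinoid patients, adjusted p = 0.14) and to the calcium sensor SCGN (0.68 ± 0.14, adjusted p = 0.42), neither of which passed. LAPTM4B was at 0.07 ± 0.27 (adjusted p = 0.90). The neuroendocrine list had a mean of 0.17 with 0 of 16 genes passing, 2 adjusted over the list alone (adjusted p = 0.027; adjusted p = 0.84 with an estimated correlation). In the closest airway alone 8 genes passed, 8 higher in carcinoid patients and 0 lower.

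The slope with distance differed between carcinoid and NSCLC patients in 8 genes, each falling more steeply in carcinoid patients (501 genes at an unadjusted p under 0.05). They were SLC6A5 (−0.39 ± 0.08, adjusted p = 0.038), GP2 (−0.36 ± 0.08), SNORD114-26 (−0.35 ± 0.08), the ghrelin receptor GHSR (−0.28 ± 0.06), the glutamate receptor subunit GRIA2 (−0.26 ± 0.06), ATP8A2 (−0.24 ± 0.05), CHGA (−0.21 ± 0.04, adjusted p = 0.016) and the potassium channel regulator ABCC8 (−0.14 ± 0.03). The neuroendocrine list had a mean slope difference of −0.10 per rank with 1 of 16 genes passing, CHGA, and 2 adjusted over the list alone. The list had an adjusted p = 3.6e-15 (adjusted p = 0.0036 with an estimated correlation). Its mean fell with distance in 3 of 3 carcinoid patients and in 10 of 20 NSCLC patients. Without 1 of the 3 carcinoid patients the slope difference of the list mean was −0.014 ± 0.028. In the 6 other lists given here 0 genes passed, 0 adjusted over the list alone, and no list passed with an estimated correlation. The mean slope difference was 0.107 for macrophage genes (adjusted p = 0.029; adjusted p = 0.81 with an estimated correlation), whose slope was 0.148 in carcinoid and 0.041 in NSCLC airways, above 0 in 3 of 3 carcinoid patients. For alveolar type 2 genes it was 0.044 and did not pass (adjusted p = 0.28; adjusted p = 0.81 with an estimated correlation), with slopes above 0 in 3 of 3. For proliferation, interferon and mast cell genes it was 0.105, 0.096 and 0.105, and for erythroid genes −0.099 (adjusted p = 1.7e-10, 6.4e-07, 0.022 and 0.0018; each adjusted p = 0.52 with an estimated correlation). Camera called 10 of 24 lists with the preset correlation and 1 with an estimated one, and fry called 1. LAPTM4B did not differ past the threshold (0.12 ± 0.08, adjusted p = 1.0). Leaving out each carcinoid patient in turn gave 0 to 17 genes (466 at an unadjusted p under 0.05 in limma where 0 passed). 0 passed without the 40% of genes with the lowest means (245 at an unadjusted p under 0.05) or without the arrays standing apart (329), and 3 passed with 1 slope per patient.

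**Figure D3:**
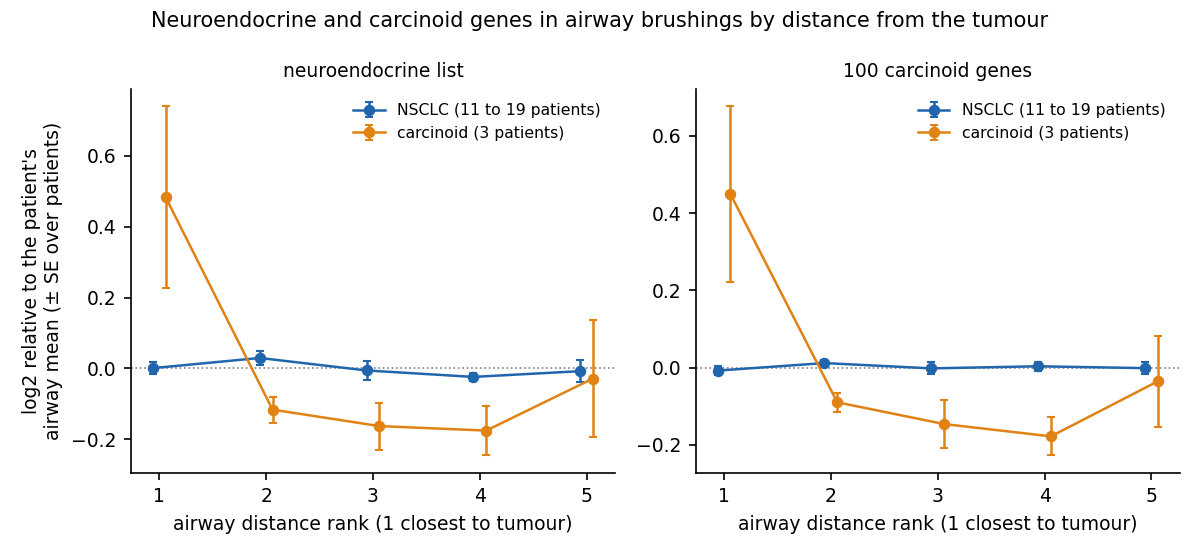
Mean log2 level of the 16 neuroendocrine genes and of the 100 genes with the highest carcinoid difference over NSCLC in airway brushings, relative to the patient's own airway mean (vertical axes, bars ± SE over patients), by distance rank (horizontal axes), in 3 carcinoid (orange) and 11 to 19 NSCLC patients (blue). The neuroendocrine mean of carcinoid patients was 0.48 ± 0.26 at rank 1 and between −0.18 and −0.03 at ranks 2 to 5.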

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

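Of the tests in this part, that of neuroendocrine cells near any tumour was chosen only after its result was seen.

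3 results stand here because an effect differed between groups by a test of the difference itself. The tumour minus normal lung difference of NSCLC patients was not the same in brushings and in tissue for 3879 genes, and chance can be excluded for that count, since 1 of 100 splits (the real one) gave as many and the highest other split gave 1467 genes. The tumour minus normal lung difference of carcinoid and NSCLC patients differed in 4234 genes, and chance can be excluded there as well (1 of 100 splits, the highest other split at 691 genes). The slope with distance differed between carcinoid and NSCLC patients in 8 genes, with a mean slope difference of −0.0991 per rank for the neuroendocrine list. For the 8 genes chance cannot be excluded, because 26 of 100 splits gave as many genes. The highest other split gave 6228. This fit on single airway arrays leaves out the spread of slopes between patients, and what gave that count was not tested.

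The fall of carcinoid genes away from the tumour was weighed for the 100 genes with the highest carcinoid difference over NSCLC, whose mean slope was −0.106 ± 0.0519 (SE) per rank in airways of the 3 carcinoid patients and 0.0030 ± 0.0052 in those of the 20 NSCLC patients. Neuroendocrine cells of the airway wall being more frequent near any tumour cannot be told apart from the rest, because the slope difference of the neuroendocrine mean rested on 1 of the 3 carcinoid patients. Without that patient it was −0.0142 ± 0.0282 (−0.504 SE), and in NSCLC airways the mean slope was −0.0089 ± 0.0088. Tumour cells or tumour RNA in the closest brushings stay open as a candidate explanation: over 1244 genes higher in carcinoids than in airways, the slope fell with the size of the tumour excess (Spearman rho −0.479 across genes, which are not independent replicates, and 0.0117 with NSCLC slopes). Taken singly, 1 of the 3 carcinoid patients had a rho below the range of the NSCLC patients (−0.140 to 0.105). That the fall rests on 1 patient stays open too, because in the pair of patients closest to 0 the mean slope was −0.0350 ± 0.0377 (−0.927 SE), although the mean fell in 3 of 3. A change of the airway cells themselves around a carcinoid is the biological explanation the design offers, and it was not tested apart from carried-over tumour RNA.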

How the results depend on the processing

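Alternatives added after the data were seen were leaving out the arrays standing apart, the pair of arrays most alike, the sample pairs that did not deviate together, airways at rank 5 or each NSCLC patient in turn, and array spread as a covariate. Over all alternatives, 142 counts and set tests of the comparisons kept their direction and their side of the threshold (counts within 1.5 times), 30 were weaker, 4 stronger and 1 reversed. Of 1653 values of 170 named gene results 1495 kept both, and of 1027 values of 85 named list results 898, 73 of the 117 weaker ones with an estimated correlation. Where no cause is given below, the cause was not tested.

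With the 40% of genes with the lowest means left out, so that fewer genes were tested, 7766 genes passed in normal lung brushings against tissue, 2735 in carcinoid against NSCLC differences and 0 in the slope difference between tumour types. Camera gave the neuroendocrine list of carcinoid against NSCLC airways the other direction, relative to the remaining genes, at a mean of 0.143. With a trended robust prior 571 genes passed for RNAlater in normal lung and 0 in tumours. With no replicate block, the patient pairing was ignored: 157 genes passed in tumour brushings against tissue, 73 and 3 for RNAlater in normal lung and in tumours, and 0 with distance, where the interferon list turned direction relative to other genes at a mean slope of −0.0108. Without the arrays standing apart 0 genes passed with distance and 0 in the slope difference. The pair most alike left out gave 466 genes for RNAlater in normal lung.

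The distance trend gave 0 genes with 1 slope per patient, 0 with the farthest against the closest airway and 0 in the patients with all 5 ranks (fewer patients), where the interferon list turned direction relative to other genes at −0.00581. With ranks scaled within patients 35 genes passed, and leaving out each patient in turn gave 0 to 1464, the 0 without 1 of the 20. Without airways at rank 5 (fewer arrays) 152 genes passed, and the mean slope of the genes lower in tumours turned to −0.0532. With an estimated correlation, the sets of genes higher and lower in tumours (mean slopes −0.0651 and 0.0431) lost their calls (adjusted p = 0.0697 and 0.131). With each carcinoid patient left out, counts ran from 0 to 6666 against normal lung, 2525 to 3651 against NSCLC, 0 to 1 in airways and 0 to 17 for the slope difference, which gave 3 genes with 1 slope per patient. In the closest airway alone 8 genes differed between airways of both tumour types. LAPTM4B in airways turned to −0.643 against normal lung tissue. Shared changes came to 471 genes with a log2 difference of 1 on both sides, by construction a subset. 1 further way of leaving out a single patient, by a property of the labels, was not given, so as to single out no one. The number of arrays limits the precision, and signal over background was not analysed here.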

Other observations

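Of the tests in this part, that of 1 patient alone behind the proliferation fall was chosen only after the result was seen.

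Most genes of cilia went opposite ways in tumours and airways. 912 genes were higher in NSCLC tumour tissue and lower in airway brushings, each against its own normal lung, and 729 were lower in tumour tissue and higher in airways, where independent lists would share 3125 genes of opposite direction. 14 of 20 ciliated cell genes were among them, such as CCDC39, which assembles the beating machinery of cilia. Its tumour difference, here averaged over collection methods and not from tissue alone, was −1.24 ± 0.21 (lower in 18 of 20 patients). In airways its difference was 2.89 ± 0.30 (higher in 18 of 19). 10 of 21 fibroblast and extracellular matrix genes were opposite, while 3 were higher and 2 lower in both. Of the 21 genes 15 fell and 3 rose in airways, the same adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.22 with an estimated correlation). These counts per list were not tested against chance.

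The fall of proliferation genes away from the tumour in NSCLC airways was weighed against 3 explanations. A different mix of ciliated and basal cells along the airways is argued against for all patients together, as far as both cell lists measure it. With both lists as covariates 90.03% of the mean slope was left (−0.0902 ± 0.0264 against −0.10 ± 0.0277 per rank). The ciliated and basal list means had slopes of 0.028 and −0.011 (permutation adjusted p = 0.63 and 0.69), so they had little to take away. The covariate fit was not repeated without single patients, and its SE is over single arrays. 1 patient alone as the whole cause stays open. Without the patient who moved it most, the list mean had a slope of −0.0423 ± 0.0197 (−2.15 SE), against −0.111 to −0.0937 without any other. That SE is over single arrays and leaves out the spread of slopes between patients, so it cannot decide. The calls of single genes ended without that patient. Tumour cells or RNA carried into the closest brushings cannot be told apart from a change of the airway: the 50 genes with the largest tumour over airway difference had a slope of −0.0500, above that of the proliferation list by 0.0502 (SE 0.0546). Carried-over RNA would make these genes fall more steeply, their tumour excess over airways being 2.61 against 0.985 for the list. The difference lay on the other side, but within 2 SE of 0. Proliferation differing along the airway wall may stay as a hypothesis beside it.

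For genes changed alike in NSCLC tumours and airways, content of the normal lung on the other side of both comparisons stays open. Of the genes lower in both, 81.1% were also lower in carcinoids, another tumour lacking alveoli, against 37.3% of all genes, with a median carcinoid difference of −0.68. Of the genes higher in both, 81.3% were higher in carcinoids against 62.7% of all genes, with a median of 0.31. Carcinoids cannot decide whether a higher share of epithelial cells in tumours and airways gives this. Of their pan-epithelial genes past the threshold, PRSS8 (−2.47 ± 0.12) and KRT19 (−2.26 ± 0.14) were lower and CDH1 (1.32 ± 0.13) higher than in normal lung. A field effect in the airways of NSCLC patients remains untested by these values, since airways of people without a tumour were not sampled.

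Of 100 splits of the samples, 1 (the real one) reached the count in each of the following. Chance can be excluded for these fits, apart from the shared changes. Splits flipped the signs of patients at random, or for distance shuffled the ranks within patients. A split that flips few patients keeps part of a real effect, and why other splits called many genes was not tested. The real and the highest other split gave 9062 and 2570 genes for NSCLC tumour against normal lung, 12355 and 7071 for airway against normal lung, and 9909 and 7577 for tumour against airway. They gave 12525 and 83 for brushings in normal lung, 5287 and 5 for brushings in tumours, 1045 and 748 for RNAlater in normal lung, 547 and 1 for RNAlater in tumours, and 782 and 88 for distance. Shared changes gave 5046 and 0, but the sign of a patient was flipped in both fits together. Those splits cannot tell whether more was shared than unrelated changes would give. The exclusion of chance for RNAlater in tumours covers the main fit alone, since 0 genes passed with a trended robust prior. For RNAlater in normal lung it covers the main fit alone too. Fewer genes than the 748 of the highest other split passed with a trended robust prior, without the pair of arrays most alike or without the patient block. No splits were drawn for those alternatives. For distance this covers the fit on single airway arrays with all patients, since 0 genes passed in limma with 1 slope per patient (2552 at an unadjusted p under 0.05), without 1 of the 20 patients (1960) or in the patients with all 5 ranks (1188). The 200 genes higher in tumours had a mean slope of −0.065 against 0.0509 in the highest other split. This too covers the fit with all patients and ranks alone. Without the airways at rank 5, for which no splits were drawn, the mean slope was −0.031. The set was not tested without the patient on whom the distance calls rested. In camera with an estimated correlation it had an adjusted p = 0.070. Chance cannot be excluded for the genes lower in tumours, where 11 of 100 splits gave a slope as large as 0.043 (highest other 0.0903). For airways of carcinoid against NSCLC patients the count in limma was 0 (2182 at an unadjusted p under 0.05). Since 100 of 100 splits must reach 0, these splits decide nothing. The highest other split gave 3501, and the cause of that count was not tested. The 3 carcinoid patients allow 4 splits, too few for a share under 0.05, with 4536 genes in the real split (1 of the 4) and 0 in the highest other.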
